A study of Mus musculus with 7 samples.

How the data were processed

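Gene expression was measured on 7 Affymetrix whole-transcript arrays of mouse embryonic fibroblasts: 3 wild-type clones, 2 clones of tenascin-C (Tnc) knockout cells, and 2 clones of wild-type cells stably transfected with a short hairpin RNA against Tnc, called knockdown here. The deposited table holds log2 signal values, 1 column per array, and every column was used. The submitters' processing notes name the affy package in R 2.8.0; the summarisation, background correction and normalization methods are not given in the sources used here. The log2 scale was read from the values, which run from 1.81 to 13.7. Array medians lay between 5.38 and 5.49, and the sorted columns differed by at most 0.158, so the arrays had been brought close to a common distribution without being made identical. No missing values and no identical columns were found. For arrays the number of replicates, not a count, limits the precision.

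Of 34760 probe sets, 22961 were listed with genes, 21640 of them with a single symbol and 1321 with several; 11799 were not listed with a gene. The 21640 single-symbol probe sets covered 19937 genes, of which 954 had several probe sets; for these the probe set with the highest mean over all arrays was used. Gene identifiers were matched to the RefSeq gene table of assembly GRCm38.p6 (21553 matched), which served only for names, gene order and chromosome membership. Genes above the 25th percentile of the array on at least 2 arrays were tested, which kept 16801.

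A linear model with a mean for each of the 3 groups was fitted across all 7 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), leaving 4 residual degrees of freedom and a prior of 2.06. Knockout and knockdown were each compared with wild type, the mean of both deficient groups was compared with wild type (called the deficient comparison), and knockout was compared with knockdown, which is also the test of whether the 2 effects differ. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are said to have risen or fallen. The p-values measure the spread between these clones. No sample label used here says that the clones of a group came from separate animals. The group comparisons, their gene and list tests, the filter, gene lists, named-gene rule and all alternatives except the 2 named below were fixed before the data were examined. The chromosome comparisons, the comparison of Tnc neighbours within chromosome 4 and some tests of explanations, named where they are reported, were chosen after values were seen.

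Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 32 lists, with an estimated correlation and fry as alternatives. The function lists were plasminogen activation and fibrinolysis, tenascins and tenascin-C receptors, interstitial matrix, basement membrane, matrix proteases and inhibitors, contractile and smooth muscle, TGF-beta and BMP response, Wnt pathway, growth factors and receptors, cell cycle, p53 targets, immortalisation loci, interferon response, MHC class I presentation, cytokines and NF-kB response, hypoxia and glycolysis, cholesterol synthesis, Hox genes, regional transcription factors, imprinted genes, glutathione and NRF2 targets, and unfolded protein response. Marker lists covered endothelial, macrophage and blood, epithelial, skeletal muscle, neural and glial, adipocyte, cartilage and bone, pericyte, and fibroblast genes. Sex-linked genes are given per array and were not tested as a list. Beside each list that passed stands the number of members past the gene test adjusted over all genes, and adjusted over the list alone; of the other lists in the comparisons with wild type, those with members called over the list alone are given.

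The genes named are Tnc, Plat, Plau and Dkk1 in every comparison; the 8 largest rises and 8 largest falls past the threshold whose arrays did not overlap between groups, filled to 5 by smallest p where fewer qualified; up to 4 called members of a list, or the 2 of smallest p where none was called; the 4 largest called differences each way between knockout and knockdown; and up to 10 genes each way called in both deficient groups. A gene and a function list that were also fixed are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Genes among the 50 annotated protein-coding neighbours on each side of Tnc were counted with Fisher's exact test, two-sided.

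Overlap between both deficient groups was set against 100 simulations of unchanged groups that share the wild-type arrays, since 3 wild-type arrays cannot be divided into separate controls of 2 each. Chromosome shifts were taken over genes with a mean log2 signal above 7, with each chromosome divided into 10 segments in gene order. Signal bias was tested with 10000 random gene lists matched in 10 bands of mean signal.

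The alternatives were no filter, a stricter filter at the 50th percentile, quantile normalization again, centring of each array on its median, a fit of only the groups compared, replicate number as a block, the trend and robust options of eBayes, array weights, every probe set tested separately, the mean of a gene's probe sets, a minimum of 2-fold, and each array left out in turn. A pair of alternatives was chosen after seeing the data: leaving out genes of chromosomes 4, 15, 18, X and Y, and leaving out both arrays numbered 2 of the deficient groups. The fit was tested on simulated data with the same design and 16801 genes. Of genes simulated with a log2 change of 1, 73.1% of 67 were called. Of those with 2, 95.5% of 67 were called, and of those with 4, 98.5% of 66, with 6 false calls (3.26%). More genes were changed in this simulation than were called in any real comparison. That makes the adjusted threshold easier to pass, so these shares may overstate what the real comparisons could detect. A list simulated with a shift of 0.5 was found with both the preset and the estimated correlation, the latter with a camera adjusted p of 0.0325, and 0 other lists were called by camera. Genes were simulated as independent of each other, so this does not test list calls among correlated genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

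Probe sets without a single gene symbol were fitted separately. Of 8710 that passed the filter, limma called 0 in each comparison, with 812, 877, 767 and 1096 at an unadjusted p under 0.05 for knockout, knockdown, deficient, and knockout against knockdown.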

Results

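The data are 7 expression arrays of spontaneously immortalised mouse embryonic fibroblasts, kept for 2 days in culture before RNA was taken: 3 wild-type clones, 2 Tnc knockout clones and 2 knockdown clones. Tnc encodes tenascin-C, a large matrix glycoprotein that modulates cell adhesion. The design asks which transcripts differ between fibroblasts that make tenascin-C and fibroblasts that lack or are depleted of it. No group carrying a control hairpin is analysed here. Values are log2 signals of 16801 tested genes, and pairs of arrays correlated at 0.979 to 0.990 over probe sets.

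Sex-linked genes differed between clones of the same group. Xist, the RNA that silences an X chromosome in female cells, had a log2 signal of 8.80 on knockout array 2 and of 3.51 to 3.77 on the other 6 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty stood at 3.77, 4.14 and 3.14 on knockout array 2 and at 5.46, 4.86 and 4.98 on knockdown array 2, against 6.06 to 8.78 on the other arrays. Both arrays numbered 2 were therefore left out together as an alternative, chosen after these values were seen.

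Tnc was strongly reduced in both deficient groups. Its mean log2 signal was 11.23 ± 0.296 in wild type (SD, n = 3), 8.28 ± 0.32 in knockout (SD, n = 2) and 6.93 ± 0.573 in knockdown (SD, n = 2). Tnc (gene identifier 21923, chromosome 4, probe set 10513739) fell 7.71-fold in knockout (log2 change -2.95 ± 0.295 SE, adjusted p = 0.042) and 19.6-fold in knockdown (-4.30 ± 0.295 SE, adjusted p = 0.0339). Where this probe set lies relative to the deleted part of the gene is not known here, so the remaining knockout signal does not measure intact transcript. The gap of 1.35 ± 0.323 SE between knockout and knockdown did not pass (adjusted p = 0.139). With any single array left out the change stayed between -3.17 and -2.72 in knockout and between -4.70 and -3.89 in knockdown, but each of these settings ended both calls.

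**Figure D1:**
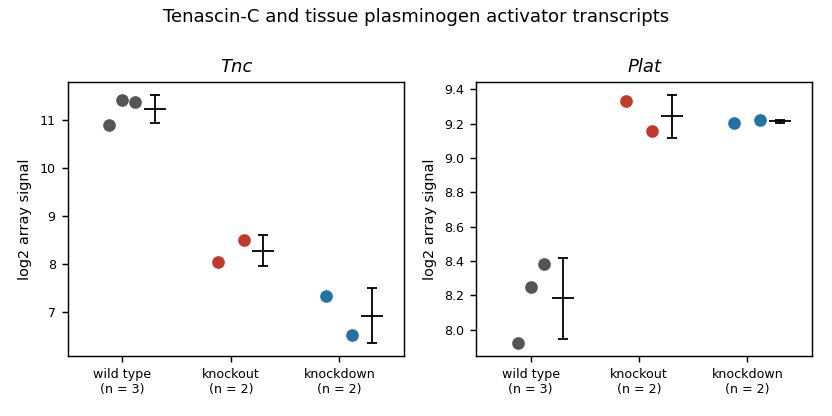
Log2 signal of Tnc and Plat on each array by group; each dot is 1 array. Tnc lies between 10.89 and 11.42 in wild type, at 8.05 and 8.51 in knockout and at 7.34 and 6.52 in knockdown, and Plat is above every wild-type array on all 4 deficient arrays.

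Plat, which encodes tissue plasminogen activator, was 2.09-fold higher in knockout (log2 1.06 ± 0.146 SE, adjusted p = 0.0712) and 2.04-fold higher in knockdown (1.03 ± 0.146 SE, adjusted p = 0.111), short of the threshold over all genes. All 4 deficient arrays, at 9.16 to 9.33, lay above the wild-type arrays at 7.92, 8.25 and 8.38. Adjusted over the list alone, Plat rose in knockout, knockdown and the deficient comparison within the plasminogen activation list. Plau, the urokinase gene, differed by 0.16 in knockout (adjusted p = 0.709) and -0.10 in knockdown (adjusted p = 0.837). Dkk1, a secreted Wnt inhibitor, differed by 0.05 (adjusted p = 0.868) and 0.03 (adjusted p = 0.91).

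In knockout compared with wild-type fibroblasts, the largest measured rise was that of Grb10, an imprinted adaptor that restrains insulin receptor signalling, at 89.6-fold (log2 6.49 ± 0.224 SE, n = 2 against 3, adjusted p = 0.00129). It stood at 11.55 and 10.73 on the knockout arrays and at 4.63, 4.70 and 4.63 in wild type. Adjacent homeobox genes of the Hoxc cluster, which set position along the body axis, rose together: Hoxc8 19.6-fold (4.29 ± 0.25), Hoxc5 19.4-fold (4.28 ± 0.247) and Hoxc6 15.6-fold (3.96 ± 0.19), with adjusted p of 0.00545, 0.00545 and 0.00393. Wild-type means of Grb10 (4.655), Hoxc5 (4.23), Hoxc6 (4.40) and Gucy1a2 (4.001) lay near the 25th percentile of the wild-type arrays (3.9997 to 4.0535), so background limits these folds. Those of P2ry10b (4.771), Hoxc8 (5.14) and Efemp1 (5.28) lay below the wild-type array medians (5.42 to 5.48). Background may limit their folds too. Efemp1, a fibulin-family matrix glycoprotein, rose 19.4-fold (4.28 ± 0.424, adjusted p = 0.042). P2ry10b, a member of a purinergic receptor family, rose 12.6-fold (3.65 ± 0.202, adjusted p = 0.00545), the tetraspanin Tspan12 5.14-fold (2.36 ± 0.202, adjusted p = 0.0246) and the guanylate cyclase subunit Gucy1a2 4.90-fold (2.29 ± 0.149, adjusted p = 0.00805).

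Among the falls in knockout, Rpl39l, a paralogue of a ribosomal protein gene, fell by a measured 18.5-fold (-4.21 ± 0.156 SE, adjusted p = 0.00129) and Mlkl, the effector of necroptosis, by 15.8-fold (-3.98 ± 0.325, adjusted p = 0.0212). Their knockout means of 3.998 and 3.981 lay at about the 25th percentile of the knockout arrays (3.9882 and 3.9775), so background limits both folds and their rank. Avpr1a, a vasopressin receptor, fell 8.98-fold (-3.17 ± 0.241, adjusted p = 0.0187). Mr1, an MHC-like antigen-presenting molecule, fell 5.14-fold (-2.36 ± 0.237, adjusted p = 0.042), and Mab21l1 5.06-fold (-2.34 ± 0.188, adjusted p = 0.0212). The interferon-induced gene Rtp4 fell 4.28-fold (-2.10 ± 0.187, adjusted p = 0.0287) and the glycosyltransferase gene Gcnt4 3.44-fold (-1.78 ± 0.16, adjusted p = 0.0287). Knockout means of Rtp4 (4.91), Mab21l1 (4.99), Mr1 (5.19) and Gcnt4 (5.378) lay below the knockout array medians (5.4129 and 5.3802). These folds may be limited by background as well. In all, 28 genes passed, 20 higher and 8 lower, with 2156 at an unadjusted p under 0.05 against 840 by chance. Each of the 28 had knockout arrays outside the wild-type range, as did 28.5% of all genes against 20% by chance. Centring each array on its median called 61 higher and 10 lower. Without wild-type array 1, 2 or 3 the count was 14, 7 or 3, without knockout array 1 or 2 it was 26 or 71, and without knockdown array 1 or 2 it was 6. Of the 28 genes, 10, 6, 3, 11, 17, 5 and 5 were among these, and without both arrays numbered 2 the count was 1. The Grb10 and Rpl39l calls each held in 18 of 19 alternatives, and that of Efemp1 in 8 of 19.

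**Figure D2:**
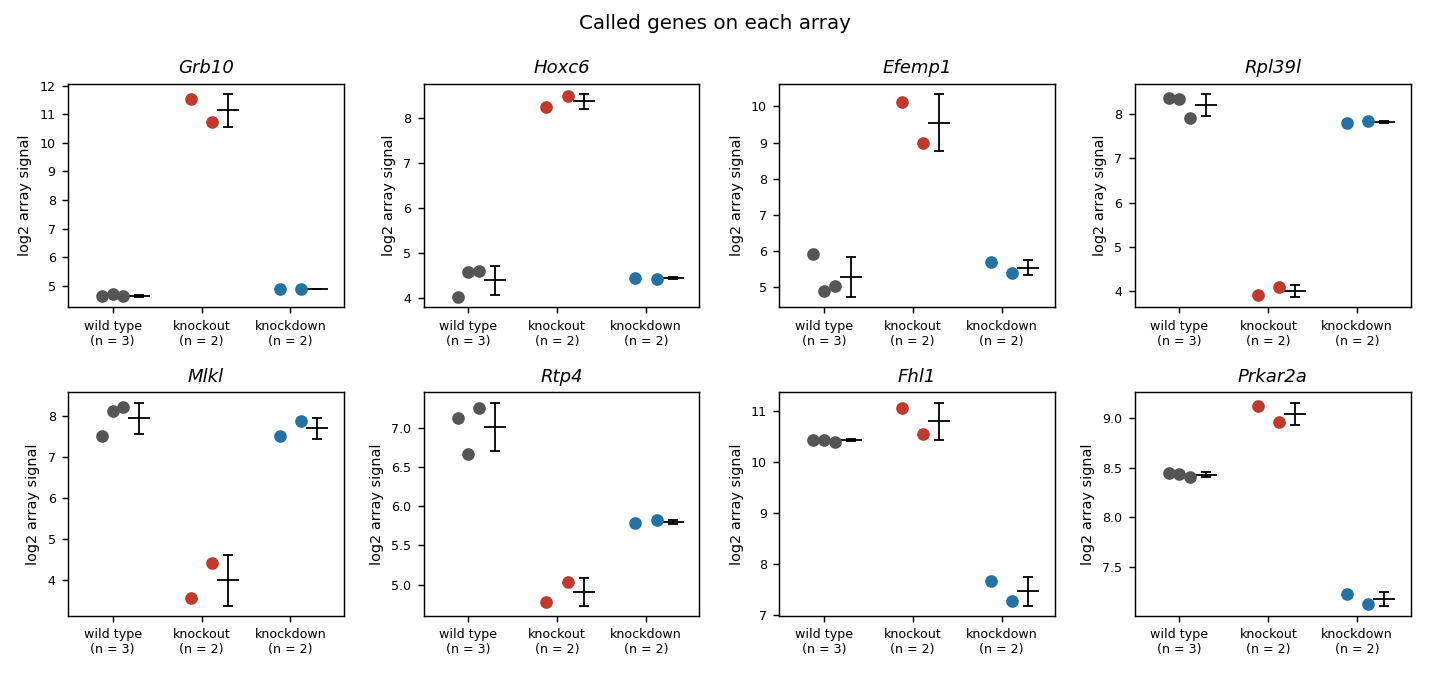
Log2 signal on each array of 8 genes called in knockout or knockdown, by group; dots are arrays and bars give the mean and SD. Grb10 lies at 11.55 and 10.73 in knockout and at 4.89 on both knockdown arrays, near the wild-type level of 4.63 to 4.70.

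Matrix and contractile genes lay higher in knockout. Of 34 interstitial matrix genes, 25 were higher and 9 lower, with a median log2 change of 0.36 (camera adjusted p = 4.84e-04; adjusted p = 0.571 with an estimated correlation). No member passed alone: limma called 0 over all genes and 0 adjusted over the list alone, with 11 higher at an unadjusted p under 0.05. Col5a1 stood at 0.98 and Col5a2 at 1.11, both genes of a fibrillar collagen. Contractile and smooth muscle genes were higher for 17 of 20 members (median 0.39, camera adjusted p = 0.00107; adjusted p = 0.554 with an estimated correlation). Neither adjustment called a member (0 by limma, 3 at an unadjusted p under 0.05), with Vcl at 0.69 and Tpm2 at 0.65. Of 19 basement membrane genes 10 were higher (list median 0.04, camera adjusted p = 0.0302; adjusted p = 0.64 with an estimated correlation). Adjusted over the list alone 2 rose, against 0 over all genes by limma and 6 at an unadjusted p under 0.05. The network collagen genes Col4a2 and Col4a1 stood at 1.30 and 1.29. Matrix proteases and inhibitors were higher for 19 of 26 members (median 0.19, camera adjusted p = 0.0399; adjusted p = 0.554 with an estimated correlation). Limma called 0 of them with either adjustment, with 5 higher and 1 lower at an unadjusted p under 0.05, Adamts5 at 2.52 and Mmp16 at -1.07. Single arrays ended some of these calls: the basement membrane adjusted p was 0.188 without wild-type array 1 and 0.187 without knockout array 1, and the contractile 0.187 without knockout array 1. The protease adjusted p was 0.227 without wild-type array 1 and 0.412 without knockout array 2. The protease call also ended with the stricter filter, quantile normalization, centring and array weights, and the basement membrane call with array weights (adjusted p from 0.0101 to 0.412 and from 0.00287 to 0.188 over 17 alternatives).

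Interferon response genes lay lower in knockout. Of 27 members 23 were lower, with a median of -0.40 (camera adjusted p = 2.41e-07; adjusted p = 0.554 with an estimated correlation). Rtp4 fell over all genes and 10 members fell adjusted over the list alone, of 12 lower at an unadjusted p under 0.05. Others lower were the RNA sensor gene Ddx58 at -1.19, the guanylate-binding protein gene Gbp7 at -1.14 and the signalling factor gene Stat2 at -0.56, these 3 chosen after their values were seen. MHC class I presentation genes were lower for 12 of 13 members (median -0.15, camera adjusted p = 0.0335; adjusted p = 0.554 with an estimated correlation). Limma called 0 of them over all genes and 0 adjusted over the list alone, with 3 lower at an unadjusted p under 0.05, Psmb8 at -0.32 and Tapbp at -0.31. The MHC call ended without wild-type array 2 (adjusted p = 0.074), wild-type array 3 (0.0943) or knockout array 1 (0.187), and also with the stricter filter and the replicate block (0.0074 to 0.187 over 17 alternatives).

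Targets of p53, a stress-induced regulator of arrest and death, lay higher in knockout for 18 of 22 members (median 0.40, camera adjusted p = 3.1e-05; adjusted p = 0.203 with an estimated correlation). By limma 0 passed over all genes and 4 rose adjusted over the list alone, of 10 at an unadjusted p under 0.05, with the death receptor gene Eda2r at 2.86 and Zmat3 at 1.26. Unfolded protein response genes were higher for 15 of 20 (median 0.14, camera adjusted p = 0.00102; adjusted p = 0.554 with an estimated correlation). Of these 0 passed over all genes by limma and 5 rose adjusted over the list alone, of 6 at an unadjusted p under 0.05, with Asns at 0.87 and Atf4 at 0.98. Hypoxia and glycolysis genes were higher for 19 of 24 (median 0.18, camera adjusted p = 0.00102; adjusted p = 0.554 with an estimated correlation). Here limma called 0 over all genes and 3 rose adjusted over the list alone, with 6 higher and 1 lower at an unadjusted p under 0.05, Ero1a at 0.98 and Ndrg1 at 1.31. Of 37 Hox genes, Hoxb2 (1.47), Hoxc5, Hoxc6 and Hoxc8 rose over all genes, and 7 rose and 2 fell adjusted over the list alone. Wild-type means of Eda2r (4.384) and Hoxb2 (5.121) lay below the wild-type array medians, so background may limit their changes too. The Hox list median was 0.07 (camera adjusted p = 0.00315; adjusted p = 0.554 with an estimated correlation). Without knockout array 2 the hypoxia and Hox lists no longer passed, and their medians fell to 0.04 and 0.009. The Hox call also ended without chromosomes 4, 15, 18, X and Y, a setting that removes the Hoxc genes of chromosome 15 from the list. Without both arrays numbered 2 the Hox, hypoxia, unfolded protein response, basement membrane and protease calls ended.

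The remaining lists did not pass in knockout. Adjusted p was 0.131 for TGF-beta and BMP response, 0.423 for the Wnt pathway, 0.767 for growth factors and receptors and 0.094 for cell cycle. It was 0.205 for immortalisation loci, 0.622 for cytokines and NF-kB response, 0.277 for cholesterol synthesis and 0.665 for regional transcription factors. It was 0.386 for glutathione and NRF2 targets, 0.296 for plasminogen activation and 0.287 for tenascins and their receptors. Of 18 imprinted genes Grb10 rose and 15 lay lower (median -0.39, adjusted p = 0.156). Adjusted over the list alone, 4 Wnt pathway genes were higher and 1 lower, 3 TGF-beta and BMP genes higher and 1 lower, and 1 imprinted gene higher and 1 lower. That adjustment also called 1 plasminogen gene (Plat) and 1 macrophage and blood gene higher, and 1 growth factor gene and 1 regional transcription factor gene lower. Among marker lists, adjusted p was 0.386 for endothelial, 0.665 for macrophage and blood, 0.808 for epithelial, 0.296 for skeletal muscle and 0.852 for neural and glial genes. Values were 0.84 for adipocyte, 0.262 for cartilage and bone, 0.543 for pericyte and 0.183 for fibroblast genes. Median, mean and test differed in sign for the endothelial, neural and glial, adipocyte, glutathione and fibroblast lists.

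In knockdown compared with wild-type fibroblasts, 3 genes fell and 0 rose. Fhl1, a LIM-domain protein of muscle and cytoskeleton, fell 7.78-fold (-2.96 ± 0.181 SE, n = 2 against 3, adjusted p = 0.0337). Prkar2a, a regulatory subunit of protein kinase A, fell 2.38-fold (-1.25 ± 0.08 SE, adjusted p = 0.0337), and Tnc was the remaining call. The next genes did not pass: the augmin subunit gene Haus6 stood at -1.13 (adjusted p = 0.0928) and the deubiquitinase gene Usp1 at -0.92 (0.0928). Higher without passing were Grina at 0.60 (0.0928), the Wnt receptor gene Fzd2 at 0.68 (0.1), Ttc30b at 0.56 (0.104), Podxl2 at 0.55 (0.108) and Tbc1d13 at 0.66 (0.11). At an unadjusted p under 0.05 limma gave 2371 genes, against 840 by chance, and 30.5% of genes had knockdown arrays outside the wild-type range against 20% by chance. The count was 0 with any of the 7 arrays left out, with 1617 to 2606 genes at an unadjusted p under 0.05 across the settings that gave 0.

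Interferon response genes lay lower in knockdown as well, for 23 of 27 members (median -0.355, camera adjusted p = 2.25e-04; adjusted p = 0.927 with an estimated correlation). By limma 0 passed over all genes and 1 fell adjusted over the list alone, of 6 at an unadjusted p under 0.05, with Rtp4 at -1.21 and Usp18 at -0.81. Relative to each gene's mean over all arrays, the interferon list median was 0.25, -0.02 and 0.40 on wild-type arrays 1, 2 and 3, -0.04 and -0.12 on the knockdown arrays and -0.275 and -0.24 on the knockout arrays, so wild-type array 2 lay close to the knockdown arrays. Contractile and smooth muscle genes were lower for 17 of 20 (median -0.26, camera adjusted p = 9.7e-04; adjusted p = 0.927 with an estimated correlation). Again limma called 0 over all genes and 1 fell adjusted over the list alone, of 3 at an unadjusted p under 0.05, with Tpm2 at -0.88 and Cnn2 at -0.35. Interstitial matrix genes were higher for 25 of 34 (median 0.50, camera adjusted p = 0.0102; adjusted p = 0.927 with an estimated correlation). Limma called 0 with either adjustment and 6 at an unadjusted p under 0.05, with Emilin1 at 1.00 and Sparc at 0.66. Cholesterol synthesis genes were higher for 16 of 18 (median 0.25, camera adjusted p = 0.0159; adjusted p = 0.927 with an estimated correlation). Either adjustment called 0 by limma, against 5 at an unadjusted p under 0.05, with Fdps at 0.36 and Srebf2 at 0.38. The matrix call ended without wild-type array 1 (median 0.21, camera adjusted p = 0.165) or 3 (median 0.44, camera adjusted p = 0.0551). It also ended without knockdown array 1 or 2, at medians of 0.51 and 0.35. The cholesterol call ended without wild-type array 3 (0.0924) or knockdown array 2 (0.184), and also without chromosomes 4, 15, 18, X and Y (0.00173 to 0.186 over 17 alternatives). Array weights and leaving out both arrays numbered 2 ended both of these calls.

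Other lists did not pass in knockdown. The plasminogen list had an adjusted p of 0.781, with Plat up and Plaur, the urokinase receptor gene, down (-0.84) adjusted over the list alone. For the Wnt pathway it was 0.298, with Fzd2 up and the Wnt modulator gene Dkk2 down (-1.23) adjusted over the list alone. Adjusted p was 0.781 for tenascins and their receptors, 0.849 for TGF-beta and BMP response, 0.781 for growth factors and receptors, 0.454 for cell cycle and 0.849 for p53 targets. Values were 0.781 for immortalisation loci, 0.781 for MHC class I presentation, 0.373 for cytokines and NF-kB response, 0.304 for hypoxia and glycolysis, and 0.0967 for Hox genes. Further values were 0.202 for regional transcription factors, 0.849 for imprinted genes, 0.865 for glutathione and NRF2 targets, 0.781 for the unfolded protein response, 0.781 for basement membrane and 0.849 for matrix proteases. Adjusted over the list alone, 1 TGF-beta gene, 1 growth factor gene, 1 p53 target and 2 hypoxia genes were lower, and 1 glutathione gene was higher and 2 lower. The fibroblast markers gave 0.0967 and the other marker lists 0.304 to 0.994. Signs of median, mean and test differed for the TGF-beta, imprinted, unfolded protein response, epithelial, skeletal muscle, and neural and glial lists.

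With both deficient groups weighed equally against wild type, 5 genes passed, 3 higher and 2 lower. Grb10 rose 10.3-fold (3.36 ± 0.188 SE, adjusted p = 0.015), a mean carried by the knockout arrays, since both knockdown arrays read 4.89. Grina, a glutamate receptor-associated membrane protein, rose 1.89-fold (0.92 ± 0.0551, adjusted p = 0.015), and Hoxc6 rose by 2.00 ± 0.159 (adjusted p = 0.0474). Rpl39l fell 4.92-fold (-2.30 ± 0.131, adjusted p = 0.015) and Tnc fell 12.3-fold (-3.62 ± 0.247, adjusted p = 0.0244). The means of Rpl39l and Hoxc6 were carried by knockout too: Rpl39l stood at 8.21 in wild type, 3.998 in knockout and 7.82 in knockdown, and Hoxc6 at 4.40, 8.36 and 4.435. All but Hoxc6 had all 4 deficient arrays outside the wild-type range, as did 7.7% of genes against 5.71% by chance. Short of the threshold were Plat at 1.05 (adjusted p = 0.106), H3c15 at 0.65 (0.0876), Arhgef10l at 0.76 (0.106), Rtp4 at -1.65 (0.0876), Dkk2 at -1.12 (0.0876) and Ddx21 at -0.56 (0.106); 2060 genes had an unadjusted p under 0.05. The count was 0 without wild-type array 1 or 2 or knockdown array 1 or 2, and 1 without wild-type array 3 or knockout array 1. Without knockout array 2 it was 5, of which 1 was among the original 5. The 0 counts came with 1265 to 2237 genes at an unadjusted p under 0.05 by limma.

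Interferon response genes were lower for 26 of 27 members in the deficient comparison (median -0.32, camera adjusted p = 1.84e-08; adjusted p = 0.775 with an estimated correlation). By limma 0 passed over all genes and 9 fell adjusted over the list alone, of 10 at an unadjusted p under 0.05, with Rtp4 at -1.65 and Ddx58 at -0.88. Interstitial matrix genes were higher for 27 of 34 (median 0.395, camera adjusted p = 1.44e-04; adjusted p = 0.775 with an estimated correlation). Limma called 0 with either adjustment and 10 at an unadjusted p under 0.05, with Col5a2 at 1.01 and Col5a1 at 0.79. Of 37 Hox genes 28 were higher, Hoxc6 rose over all genes and 6 rose adjusted over the list alone (median 0.12, camera adjusted p = 5.16e-04; adjusted p = 0.775 with an estimated correlation). Targets of p53 were higher for 17 of 22 (median 0.16, camera adjusted p = 0.0164; adjusted p = 0.775 with an estimated correlation), a shift carried by knockout (median 0.40), since the knockdown median was -0.02 with 10 higher and 12 lower. Both adjustments called 0 by limma, with 6 higher and 1 lower at an unadjusted p under 0.05, Eda2r at 1.41 and Zmat3 at 0.57. Cholesterol synthesis genes were higher for 15 of 18 (median 0.13, camera adjusted p = 0.024; adjusted p = 0.775 with an estimated correlation). Limma again called 0 with either adjustment, with 4 at an unadjusted p under 0.05, Srebf2 at 0.42 and Hmgcs1 at 0.34. Without knockout array 2 the Hox (0.0566), p53 (0.0652) and cholesterol (0.442) calls ended. So did p53 without wild-type array 1 (0.0516) and cholesterol without wild-type array 3 (0.12) or knockdown array 2 (0.123). Without both arrays numbered 2 the Hox, p53 and cholesterol calls ended, and with the stricter filter the p53 and cholesterol calls. The p53 call also ended in the fit of only the groups compared (0.0093 to 0.271 over 17 alternatives), and the cholesterol call with the replicate block, with array weights and without the 5 chromosomes (2.51e-04 to 0.852). The number of lists called was 9 without wild-type array 2 and 3 without knockout array 2, against 5 with all arrays.

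**Figure D3:**
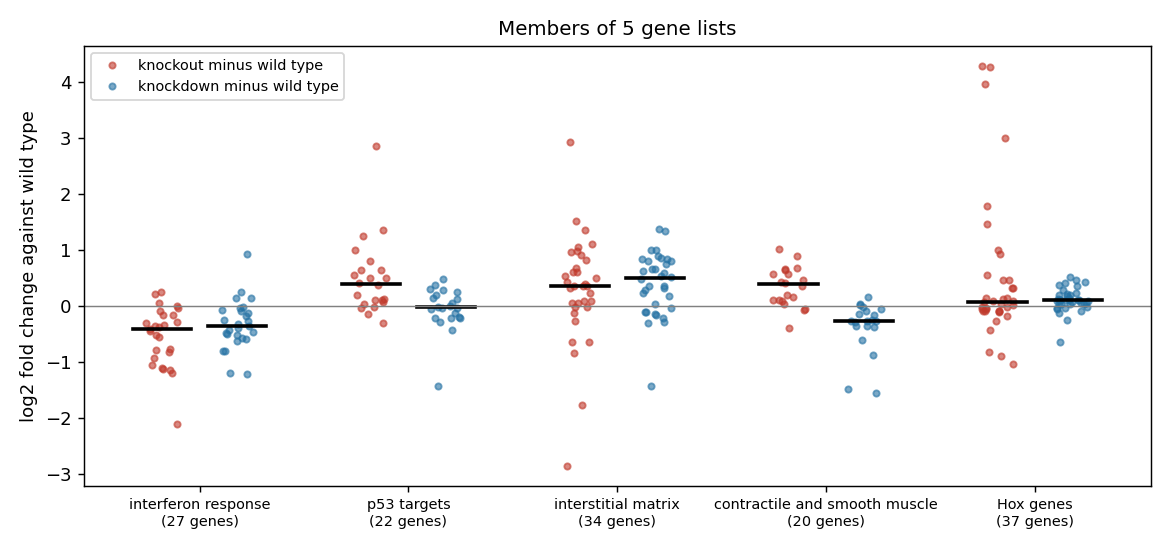
Log2 change against wild type of each member of 5 gene lists, with knockout in red, knockdown in blue and the list median in black. The interferon response medians lie at -0.40 in knockout and -0.355 in knockdown, while the contractile medians lie at 0.39 and -0.26.

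In the deficient comparison the plasminogen list had an adjusted p of 0.874, with Plat up and Plaur down (-0.49) adjusted over the list alone. Adjusted p was 0.442 for tenascins and their receptors, 0.499 for TGF-beta and BMP response, 0.218 for the Wnt pathway, 0.473 for growth factors and receptors and 0.0923 for cell cycle. Values were 0.611 for immortalisation loci, 0.473 for MHC class I presentation, 0.405 for cytokines and NF-kB response, 0.351 for hypoxia and glycolysis, and 0.299 for regional transcription factors. They were 0.469 for imprinted genes, 0.587 for glutathione and NRF2 targets, 0.18 for the unfolded protein response, 0.0923 for basement membrane, 0.299 for matrix proteases and 0.941 for contractile genes. Adjusted over the list alone, 2 Wnt pathway genes were higher and 1 lower, and 1 gene each of the tenascin, imprinted and glutathione lists was higher. Fibroblast markers gave 0.0923 and the other marker lists 0.499 to 0.968. Signs of median, mean and test differed for the contractile, endothelial, epithelial, and cartilage and bone lists. No list call held with an estimated correlation in any comparison (0 of 32 by camera each time). Fry, which tests whether a list moves on balance in a single direction, called p53 targets alone, in knockout (adjusted p = 0.0138, 18 of 22 members higher, median 0.40), the deficient comparison (0.0278) and knockout against knockdown (0.0301).

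Knockout and knockdown cells differed from each other in 63 genes, 46 higher and 17 lower in knockout, with 3011 at an unadjusted p under 0.05. Grb10 was 76-fold higher in knockout than in knockdown (log2 6.25 ± 0.246 SE, n = 2 against 2, adjusted p = 0.00361), Hoxc5 20.1-fold (4.33 ± 0.27), Hoxc8 18-fold (4.17 ± 0.274) and Efemp1 16.2-fold (4.02 ± 0.464). Avpr1a was 21.7-fold lower (-4.44 ± 0.264), Rpl39l 14.1-fold (-3.82 ± 0.171), Mlkl 13.3-fold (-3.73 ± 0.356) and Mr1 9.25-fold (-3.21 ± 0.259). Background limits the folds of Rpl39l and Mlkl, with knockout means of 3.998 and 3.981. It also limits those of Grb10 and Hoxc5, with knockdown means of 4.89 and 4.18. Means of Hoxc8 in knockdown (5.262) and Mr1 in knockout (5.192) lay below the array medians, so background may limit their folds too. Plat differed by 0.03 (adjusted p = 0.936), Plau by 0.25 (0.475) and Dkk1 by 0.01 (0.969). All 63 genes had non-overlapping arrays, as did 45% of genes against 33.3% by chance. The count was 16, 12 and 7 without wild-type arrays 1, 2 and 3, and 26 and 103 without knockout arrays 1 and 2. It was 12 without knockdown array 1 and 0 by limma without knockdown array 2, with 2557 genes at an unadjusted p under 0.05; without both arrays numbered 2 it was 1.

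Contractile and smooth muscle genes were higher in knockout than in knockdown for 19 of 20 members (median 0.50, camera adjusted p = 1.51e-07; adjusted p = 0.698 with an estimated correlation), with 1 member called over all genes and 1 adjusted over the list alone. Hypoxia and glycolysis genes were higher for 15 of 24 members (median 0.21, camera adjusted p = 6.16e-04; adjusted p = 0.715 with an estimated correlation), with 2 called over all genes and 6 adjusted over the list alone. Targets of p53 had a median of 0.40 (camera adjusted p = 6.13e-04; adjusted p = 0.367 with an estimated correlation), with 0 called by limma over all genes (10 higher and 2 lower at an unadjusted p under 0.05) and 7 higher and 1 lower adjusted over the list alone. The unfolded protein response list (median 0.17, camera adjusted p = 6.13e-04; adjusted p = 0.715 with an estimated correlation) was also higher in knockout. Limma called 0 of its members over all genes, with 8 at an unadjusted p under 0.05, and 6 adjusted over the list alone. The other 27 lists did not pass (adjusted p from 0.0656 to 0.943).

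Tnc, the gene targeted in both deficient groups, was the only gene called in the same direction in both. Simulated unchanged groups sharing the wild-type arrays gave 0.02 such genes on average. The call of the targeted gene itself is no evidence of a wider overlap. At an unadjusted p under 0.05, 406 genes moved the same way in both groups, against a simulated mean of 208.6 and maximum of 247, and 108 moved opposite ways, against 15.81. The log2 changes of both groups correlated at 0.301 across genes, which are not independent replicates, against a simulated 0.399 from shared controls alone; their covariance was 0.0316 against 0.0181. The shared wild-type arrays contribute to both measures. Genes were simulated as independent, so the simulated range does not allow for genes that vary together, and this comparison cannot exclude chance.

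Genes next to Tnc on chromosome 4 were compared with other genes. Among 59 tested neighbours of 100, limma called 0 in knockout and 0 in knockdown, with 14 and 23 at an unadjusted p under 0.05. Neighbours lower at that level made up 16.9% in knockout against 5.45% of other genes (Fisher's exact p = 0.00129) and 37.3% in knockdown against 6.88% (Fisher's exact p = 2.25e-11), with medians of -0.06 and -0.17. Against the other 985 tested genes of chromosome 4, a comparison chosen after the values were seen, more neighbours were lower at that level in knockout (16.9% against 7.31%, Fisher's exact p = 0.0202), although their median of -0.06 was not below the -0.08 of the others, and in knockdown the difference did not pass (37.3% against 26.3%, Fisher's exact p = 0.0704).

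Whole chromosomes also shifted between groups at the preset correlation, and several of the genes above lie on them. That test treats genes of a chromosome as nearly independent, and it called most of the 20 chromosomes in knockout and in knockdown. No chromosome passed with an estimated correlation (camera adjusted p of 0.377 or more against wild type), so the test does not single out those named. In knockout, 98% of 303 chromosome 15 genes were higher (median 0.48, in 10 of 10 segments; 0.37 and 0.57 on the 2 arrays; camera adjusted p = 5.54e-45; adjusted p = 0.377 with an estimated correlation). It was higher in knockdown too, for 83.8% of genes (median 0.20; 0.15 and 0.30 on the 2 arrays; camera adjusted p = 2.16e-14; adjusted p = 0.795 with an estimated correlation). Chromosome 15, which carries Hoxc5, Hoxc6, Hoxc8 and Grina, held 7 of the 28 called genes against 4.15% of those tested (Fisher's exact p = 1.13e-04). This test counts adjacent Hoxc genes as independent, so the excess is not separate evidence of a whole-chromosome shift. Atf4, Ndrg1 and Srebf2, given above as list members, also lie there, where the median was 0.34 in the deficient comparison. In knockout, chromosome 19 was higher (median 0.29, 93.7% of genes; 0.12 and 0.43 on the 2 arrays; camera adjusted p = 3.01e-15; adjusted p = 0.812 with an estimated correlation). Lower there were chromosome 5 (median -0.20, 80% of genes; -0.29 and -0.105 on the 2 arrays; camera adjusted p = 4.35e-11; adjusted p = 0.812 with an estimated correlation) and, by less, chromosome 4 (median -0.10, 69% of genes; camera adjusted p = 1.89e-04; adjusted p = 0.812 with an estimated correlation). On wild-type arrays 1, 2 and 3 chromosome 5 stood at 0.16, -0.08 and -0.07, so knockout array 2 lay close to wild-type arrays 2 and 3. Chromosome 4 stood at -0.04 and -0.15 on the knockout arrays, the former inside the wild-type range, which reached -0.09. Chromosome 18 was lower in knockout (median -0.26; -0.35 and -0.20 on the 2 arrays; camera adjusted p = 6.97e-21; adjusted p = 0.377 with an estimated correlation) and higher in knockdown (median 0.20; 0.21 and 0.19 on the 2 arrays; camera adjusted p = 1.52e-11; adjusted p = 0.607 with an estimated correlation). It held 9 of the 63 genes that differed between knockout and knockdown, against 2.4% of those tested (Fisher's exact p = 1.85e-05). In knockdown, 89% of 435 chromosome 4 genes were lower (median -0.39, in 10 of 10 segments; -0.41 and -0.30 on the 2 arrays; camera adjusted p = 8.48e-27; adjusted p = 0.607 with an estimated correlation). Tnc, Haus6 and Usp1 lie on this chromosome, as do the list members Tpm2 and Ddx58. Chromosome 2 was higher in knockdown (median 0.27; 0.23 and 0.35 on the 2 arrays; camera adjusted p = 1.68e-29; adjusted p = 0.607 with an estimated correlation). Chromosome X, which carries Fhl1, P2ry10b and Eda2r, was lower there (median -0.22; -0.04 and -0.35 on the 2 arrays; camera adjusted p = 3.37e-07; adjusted p = 0.795 with an estimated correlation). Leaving out chromosomes 4, 15, 18, X and Y left 11 genes in knockout, all 11 among the 28. It left 0 in knockdown by limma (1791 at an unadjusted p under 0.05), 2 in the deficient comparison and 22 between knockout and knockdown. The setting removed called genes themselves, among them Tnc, Fhl1, Grina and Hoxc6, so it does not test their calls.

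**Figure D4:**
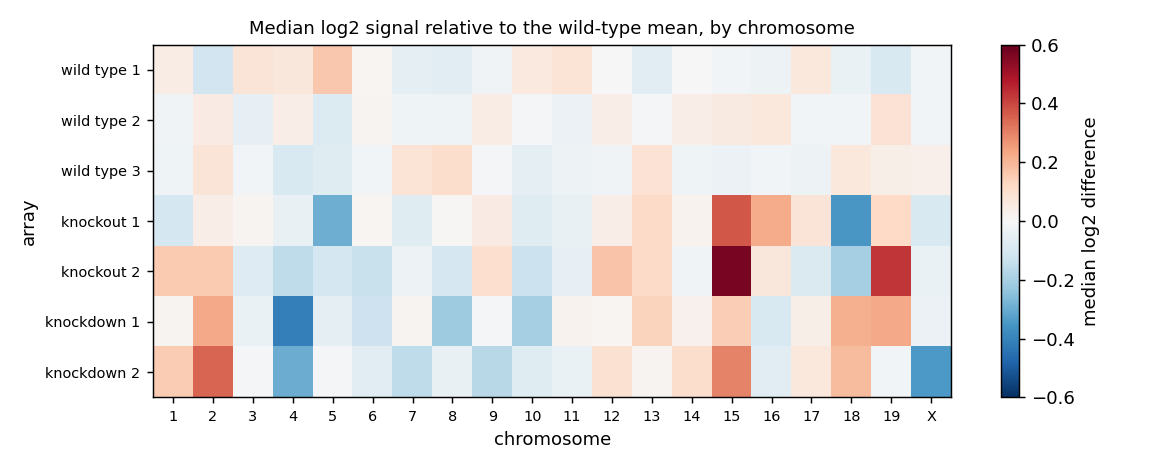
Median log2 signal relative to the wild-type mean by chromosome and array, after subtraction of each array's median over all genes, for genes with a mean log2 signal above 7. Chromosome 15 stands at 0.37 and 0.57 on the knockout arrays, and chromosome 4 at -0.41 and -0.30 on the knockdown arrays.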

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

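The 3 tests on the Hoxc genes and the tests of copies and of transcript loss on chromosome 4 were chosen only after the results were seen. The knockout and knockdown effects differed, by a test of the difference itself, in 63 genes. In knockout minus knockdown log2, the genes named were Grb10 at 6.25, Hoxc5 at 4.33, Hoxc8 at 4.17, Efemp1 at 4.02, P2ry10b at 3.99, Hoxc6 at 3.92, Tspan12 at 2.56, Gucy1a2 at 2.42, Arhgef10l at 0.924, Haus6 at 0.873 and Grina at 0.629. Rpl39l stood at -3.82, Mlkl at -3.73, Avpr1a at -4.44, Mr1 at -3.21, Mab21l1 at -2.77 and Gcnt4 at -1.71, with adjusted p from 0.00361 to 0.0495 over all these genes. Fhl1 at 3.34 (adjusted p = 0.0062) and Prkar2a at 1.86 (adjusted p = 0.00361) were lower in knockdown. List medians of the difference were 0.502 for contractile, 0.401 for p53 target, 0.213 for hypoxia and glycolysis and 0.173 for unfolded protein response genes, and 0 of these calls held with an estimated correlation in camera.

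In knockout the 5 Hoxc genes from Hoxc4 to Hoxc9 were higher by 1.78 to 4.29, with a median of 3.96. Loss of the Tnc transcript in cultured cells, as the whole cause, would move them in knockdown too. There their median change was 0.0401 (median SE 0.248), below the bound of 1.98 set for such a cause (0.5 of the knockout change). The tables argue against such a cause. Loss of Tnc before the cells were cultured cannot be tested this way, since the hairpin was put into wild-type cells. Extra copies of chromosome 15 are argued against as the whole cause, since these genes lay 3.48 above the other genes of that chromosome, whose median was 0.483 with an SD of 0.396. A different body position or animal of origin of the knockout lines may account for it. Origin and knockout cannot be told apart, because every knockout array shares both. Of the 5 arrays of wild-type origin, 0 had Hoxc6 at the knockout level. This count decides nothing, since Hoxc6 was already known to be higher in knockout than in both other groups.

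Chromosome 4 genes were lower in knockdown, with a median log2 change of -0.39. A bias with mean signal is argued against, since the lowest of 10000 random lists matched on signal had a median of -0.0878. Fewer copies of chromosome 4 in the knockdown clones stay open and cannot be told apart from other causes: 10 of 10 segments were lower, but so were those of 6 other chromosomes with medians of only -0.219 to -0.0998, so this count decides nothing. Loss of the Tnc transcript stays open too: taken as the mean of the array shifts, chromosome 4 moved by -0.104 in knockout and -0.36 in knockdown, against a bound of -0.18 (0.5 of the latter), with an SE of 0.0741. No DNA was measured in the data used here.

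Interferon response genes were lower in the deficient comparison by a list median of -0.318. A single high wild-type array is argued against, since the median nearest 0 with each wild-type array left out was -0.255. Leaving out a single array each time cannot test whether wild-type arrays 1 and 3 carry the shift together. Relative to each gene's mean they stood at 0.254 and 0.399, and wild-type array 2 at -0.017, near knockdown array 1 at -0.0399. A bias with mean signal is argued against, since the lowest matched random list had a median of -0.0973. Chance is not excluded: 2 of the 35 splits of the 7 arrays into 3 and 4 gave a median as low, the other at -0.3318 with wild-type arrays 1 and 3 and knockdown array 1 as the group of 3. An effect of tenascin-C loss may be among the open explanations, as may differences between clones.

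The 5 genes called in the deficient comparison were set against 100 arrangements drawn from those of the 7 arrays into 3, 2 and 2; only the real arrangement (1 of 100) gave as many, the highest other count being 2. By this share alone chance would be excluded, but the other arrangements mix the groups, so real differences between knockout and knockdown widen their spread and hold their counts down. The real count is also 0 by limma without wild-type array 1 or 2 or knockdown array 1 or 2, with 1265, 1696, 2237 and 1839 genes at an unadjusted p under 0.05.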

How the results depend on the processing

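Leaving out chromosomes 4, 15, 18, X and Y and leaving out both arrays numbered 2 were chosen only after the results were seen. No called result changed direction. Of the values for named genes across alternatives, 4011 kept their direction and side of the threshold, 225 lost and 25 gained the call, and 14 changed sign without a call; for gene lists these were 762, 89, 18 and 43. Where a cause is not given by the setting itself (fewer genes, fewer arrays), the cause was not tested.

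With an estimated correlation camera called 0 lists in knockout, 0 in knockdown and 0 in the deficient comparison, and fry called 1, 0 and 1. Without a filter, 38 genes differed between knockout and knockdown, 0 genes were called in both groups, and Tnc stood at -2.95 (adjusted p = 0.0539) and -4.30 (0.0577). The stricter filter gave 79 genes in knockout, 10 in the deficient comparison, 111 between knockout and knockdown and 3 deficient lists. Quantile normalization gave 45 and 100 genes in knockout and between knockout and knockdown, and centring 71 and 137. A fit of only the groups compared gave 6, 0, 0 and 0 genes in knockout, knockdown, deficient, and knockout against knockdown, 0 shared, and Tnc at -2.95 (0.08) and -4.30 (0.144). Trend and robust options gave 70 in knockout and 13 deficient; array weights gave 8 deficient, 18 between knockout and knockdown and 2 knockdown lists; probe sets tested separately and a 2-fold minimum each gave 39 between knockout and knockdown. Leaving out the 5 chromosomes removed Tnc, the only shared gene, and also Fhl1, Grina and Hoxc6 before testing, so it cannot test their calls. With that setting the counts were 11, 0, 2 and 22, with 0 shared. Without both arrays numbered 2 they were 1, 0, 0 and 1, with 0 shared, Tnc at -3.17 (0.156) and -3.89 (0.244), and 6, 2 and 3 lists.

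Replicate numbers did not pair the arrays (correlations of same-number arrays -0.0738 to 0.199). With replicate number as a block the counts were 2, 0, 0 and 2, with 0 shared, Tnc at -2.87 (0.274) and -4.22 (0.286), and 9 knockdown lists.

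With each array left out in turn the counts ranged from 3 to 71 in knockout, were 0 in knockdown throughout, and ranged from 0 to 5 in the deficient comparison and from 0 to 103 between knockout and knockdown, with 0 shared. Tnc ranged from -3.17 to -2.72 in knockout and from -4.70 to -3.89 in knockdown, and lists from 2 to 5 in knockdown and from 3 to 9 in the deficient comparison. A group left with a single array is assumed to vary like the others. For limma, the settings with 0 genes had 1617 to 2606 genes at an unadjusted p under 0.05 in knockdown, 1265 to 2253 in the deficient comparison, and 2216 to 2557 between knockout and knockdown. At the preset correlation, the interferon lists passed camera in 17 of 17 other alternatives in each comparison with wild type, and interstitial matrix and p53 targets in knockout in 17 of 17. The estimated correlation ended these calls, with adjusted p of 0.554, 0.927 and 0.775 for interferon in knockout, knockdown and the deficient comparison, 0.571 for matrix and 0.203 for p53. List tests were not run for separate probe sets, the mean of probe sets or the 2-fold minimum. Genes near the array background carry little signal, and folds to or from it are compressed.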

Other observations

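Some measured genes outside the called sets moved far but unevenly between clones. Mest, an imprinted gene of embryonic mesoderm, stood at 6.17 and 5.69 on the knockout arrays and at 9.05, 9.55 and 7.53 in wild type, a log2 change of -2.78 that did not pass over all genes; it was chosen after its values were seen. Gap43, a growth cone protein gene in the neural and glial list, had a log2 change of -4.30 ± 1.03 SE in knockout (adjusted p = 0.185) and -2.72 ± 1.03 SE in knockdown (adjusted p = 0.323). The keratin gene Krt19 stood at -1.67 in knockout (adjusted p = 0.515) and -2.47 in knockdown (adjusted p = 0.332). Its knockout clones differed widely (SD 2.53), whereas the knockdown clones lay close together (SD 0.274). The fit uses a single spread for all groups, so the knockout clones weakened the knockdown test too.

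Dkk2, a modulator of Wnt signalling, was lower by log2 -1.02 ± 0.13 SE in knockout (adjusted p = 0.0668) and -1.23 ± 0.13 SE in knockdown (adjusted p = 0.0928), and fell adjusted over the list alone in both. The growth factor gene Ereg stood at -2.74 in knockdown (adjusted p = 0.183) and Igfbp3, a carrier of insulin-like growth factors, at -1.69 in knockout (adjusted p = 0.117). Meis2, a cofactor of Hox proteins, stood at -1.55 in knockout (adjusted p = 0.0686) and fell adjusted over the list alone.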
